A study of Homo sapiens with 6 samples.

How the data were processed

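Total RNA of HEK293 cells was made into libraries with a directional kit, per the labels' protocols, with 3 libraries from wild-type cells and 3 from CNBP knockout cells. TopHat, Cufflinks, Cuffdiff and the genome build hg19 are named in the submitters' processing notes, without versions. The strand setting of the counting and the annotation are not given in the sources used here. Nothing in the labels says whether the 3 libraries of a group came from separate cultures or clones.

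The authors' deposited table holds 1 value per gene for wild type and 1 for knockout. These FPKM values, fragments per kilobase of transcript normalised to the mapped fragments, were computed and deposited by the authors, who name Cufflinks and Cuffdiff per the submitters' processing notes. No header names the unit, which was inferred from those tools and from the size of the values, with sums of 612366 and 612941. How the 3 libraries of a group were combined is not given in the sources used here. The table also holds a deposited log2 ratio of wild type over knockout, which equals the ratio of the 2 values for the 16867 genes above 0 in both groups and is an error code in 368 cells. All ratios in the text were computed from the 2 values in the opposite sense, knockout over wild type. The low values showed no steps of whole reads, so that no depth was recovered from them, and a listed 0 can be a failed estimate.

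Of 19892 genes, 19130 had an Ensembl ID in the name table used. The symbols of 26 genes had been turned into date numbers and were restored from the Ensembl ID. In all, 2350 genes were at 0 in both groups, 368 in wild type alone and 307 in knockout alone. Genes with an FPKM of at least 1 in one group were compared (13221), of which 13219 were above 0 in both. No pseudocount was used for the main ratios.

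The tests chosen before the data were examined, an adjusted p under 0.05 from the authors' table or a linear model on values per library, need p-values or values per library and were not run. In their place a gene was counted at a fold of 1.5 or more, a threshold chosen after the data were seen. No p-value, standard deviation or replicate check is given for any difference. With 1 value per group, a difference between the columns cannot be set against the spread between libraries.

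Genes were named by a rule fixed before the data were examined, with the fold in place of the test: CNBP; the 10 highest and 10 lowest ratios among counted genes with an FPKM of at least 5 in one group; up to 4 counted members of each list with the largest absolute ratio, or else its 2 most abundant members; the 3 most abundant counted genes in each direction; and any gene at 0 in one group and at least 5 in the other. Other genes named are said to have been chosen after their values were seen. Some genes that the rule names are not reported here.

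The 36 gene lists were fixed at the same time. For each, random lists of the same size were drawn 10000 times from the compared genes in 20 bins of mean FPKM, and the list's median log2 ratio was given as a percentile of theirs. Lists with fewer than 5 measured genes are described by their members. Some lists share genes: the mesenchymal list shares 2 with the neural crest list and 2 with the TGF-beta targets, the RNA helicase list shares 2 each with the MYC list and the translation factors, and 5 other pairs share 1 gene. In a test on simulated data with 13219 genes, lists of 30 genes with no shift lay outside the central 95% in 4% of 200 draws, lists shifted by 0.1 in 67% and lists shifted by 0.2 in 99.5%. The simulated genes varied independently, and several fixed lists had fewer than 30 measured genes, so that these shares need not hold for them.

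Coding sequences, gene order and overlaps were taken from GENCODE release 29 by Ensembl ID. That release is on another build than the one the submitters name, so no coordinates are given, and overlaps may differ from the authors' annotation. The longest coding sequence of each gene was searched for TGGAG, a motif chosen before the data were examined, and 98.8% of compared genes had one. For the gene order, genes were set in non-overlapping windows of 40, and the order was shuffled 1000 times. To remove regional shifts, the median of the 20 nearest genes was taken off each log2 ratio.

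The alternatives were an FPKM minimum of 5 or none, pseudocounts of 1 and 0.1, centring on the median, small non-coding RNA genes left out, random lists matched on transcript length, and the shortest coding sequence. Added after the data were seen were a 2-fold threshold, pseudocounts for the counts of genes, the neighbours' median taken off, and clone-named and readthrough genes left out. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.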

Results

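RNA was sequenced from HEK293 cells, a human line derived from embryonic kidney, in which the gene CNBP had been disrupted with CRISPR-Cas9, and from wild-type HEK293 cells. CNBP is a nucleic-acid-binding protein with CCHC zinc knuckles. The title of the series concerns its binding to G-rich elements in the coding sequences of mRNAs and their translation. The 6 libraries fall into 2 groups of 3, wild type and CNBP knockout. The table analysed here gives 1 FPKM value per gene and group, made by the authors, so that no spread between the 3 libraries of a group, standard error or p-value accompanies any value below. The depth of the libraries is unknown. Ratios are given as log2 of the knockout value over the wild-type value, and the terms knockout column and wild-type column refer to the labels of the 2 values.

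CNBP mRNA itself was not lower in the knockout column. Its FPKM was 202 in wild type and 214 in knockout, a log2 ratio of 0.09. Small insertions and deletions made by Cas9 can inactivate a gene without lowering its mRNA, so this value does not check the labels of the 2 columns. Every direction below therefore rests on the label of the column and not on the CNBP value.

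The 2 columns were close to each other. Of 13219 genes with an FPKM of at least 1 in one group and above 0 in both, 10339 (78.2%) lay within 1.2-fold, and the median log2 ratio was -0.01. Across genes, which are not independent replicates, Spearman's rho between the columns was 0.993. At a fold of 1.5 or more, 196 genes were higher and 368 lower in the knockout column. Most of these had low values: among the 2785 genes with a mean FPKM from 1 to 5, 124 were higher and 218 lower, and the central 95% of log2 ratios ran from -0.86 to 0.72. Among the 2528 genes with a mean FPKM of 50 or more, 3 were higher and 12 lower, and the central 95% ran from -0.35 to 0.32. The counts depend on the minimum: with an FPKM of at least 5 in one group they were 53 higher and 126 lower. DEFB136, at 1.04 FPKM in wild type, and L34079.2, at 1.83 FPKM in knockout, were listed at 0 in the other group. Both were named after their values were seen.

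**Figure D1:**
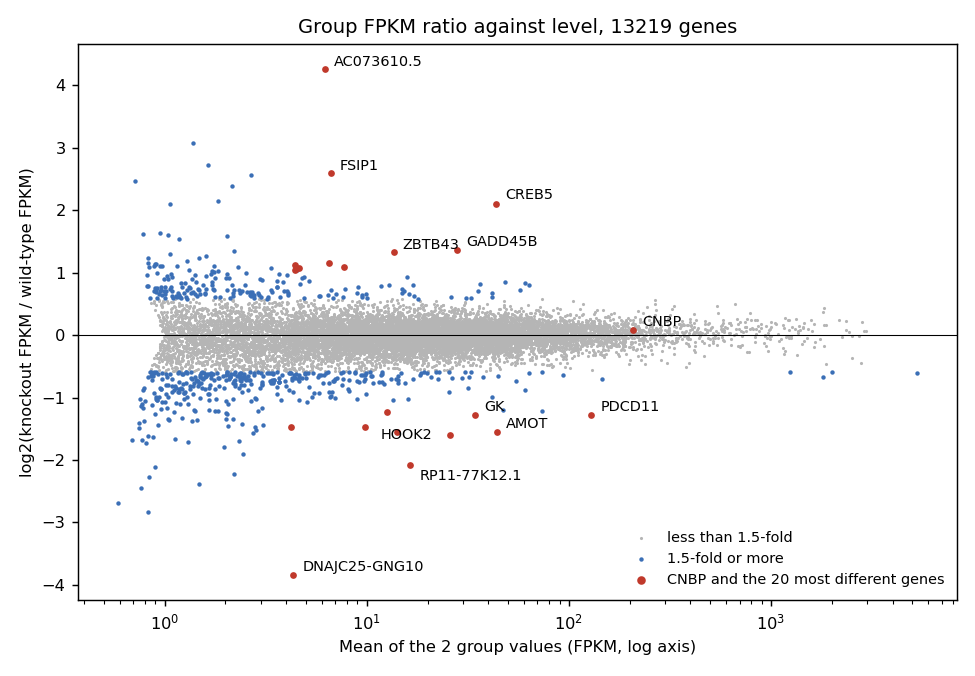
Each point is a gene with an FPKM of at least 1 in one group. The horizontal axis is the mean of the 2 group FPKM values (log axis) and the vertical axis the log2 ratio of knockout over wild type. Blue points differ by 1.5-fold or more, and red points are CNBP and the 10 highest and 10 lowest ratios among genes with an FPKM of at least 5 in one group. Ratios spread more widely at low FPKM, and CNBP lies at 0.09.

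CREB5, a transcription factor that binds cAMP response elements, had the highest ratio of the genes above 10 FPKM in both columns, with 16.6 FPKM in wild type and 71.1 in knockout, a 4.29-fold difference. GADD45B, a stress-inducible gene, went from 15.6 to 40.4 FPKM (2.59-fold), and the zinc-finger gene ZBTB43 from 7.76 to 19.5 FPKM (2.51-fold). FSIP1 went from 1.89 to 11.4 FPKM, a log2 ratio of 2.59. It overlaps the far more abundant THBS1 on the opposite strand, and the strand setting of the counting is not given in the sources used here. DHRS2, a short-chain dehydrogenase, had a log2 ratio of 1.08 and RAMP2, a receptor activity-modifying protein, 1.05, both from under 3 FPKM in wild type. The other 4 of the 10 highest ratios belong to gene models that overlap neighbours on the same strand, so that reads cannot be assigned with certainty. These are AC073610.5 (log2 ratio 4.26), RP11-162P23.2 (1.16), RP4-539M6.19 (1.13) and the readthrough PTGES3L-AARSD1 (1.09).

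Among the lowest ratios, AMOT, which encodes the junction-associated protein angiomotin, had 65.7 FPKM in wild type and 22.4 in knockout, a 2.93-fold difference. PDCD11, a factor in ribosomal RNA processing, went from 183 to 75.7 FPKM (2.42-fold), and GK, glycerol kinase, from 48.7 to 20.1 FPKM (2.43-fold). PAFAH2, a phospholipase that acts on platelet-activating factor, had a log2 ratio of -1.47, GDPD3 of -1.47 and FAM213A of -1.24. HOOK2, which encodes a protein that links cargo to microtubule motors, went from 38.7 to 12.7 FPKM (3.04-fold). It overlaps JUNB, RNASEH2A and MAST1 on the opposite strand and PRDX2 and RTBDN on the same strand. Gene models that share exons or span with neighbours also appear here: the readthrough DNAJC25-GNG10 (8.11 to 0.566 FPKM, log2 ratio -3.84), RP11-77K12.1 (-2.08) and CTD-2545G14.7 (-1.55). GDPD3 and RP11-77K12.1 lie on chromosome 16, whose genes had a median log2 ratio of -0.12. AMOT and GK lie on the X chromosome, whose median was -0.07. With the median of the 20 nearest neighbours taken off, GK had a log2 ratio of -1.13 against -1.28 before. That of AMOT was -1.54 against -1.55.

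The 3 most abundant genes that were higher by 1.5-fold were RAPGEF6, an exchange factor for Rap GTPases (46.4 to 80.9 FPKM), HAGHL (43.8 to 78.0 FPKM) and DDIT4, an inhibitor of mTORC1 signalling (43.2 to 71.2 FPKM). RAPGEF6 overlaps another gene model on its strand, and HAGHL overlaps CCDC78 and NARFL on the opposite strand. HAGHL lies in a part of chromosome 16 where genes were shifted upward, unlike most of that chromosome, and its log2 ratio of 0.83 was 0.65 with the median of its 20 nearest neighbours taken off. The 3 most abundant that were lower were mitochondrially encoded: MT-ATP8 (6409 to 4210 FPKM, log2 ratio -0.61), MT-ND3 (2400.0 to 1596 FPKM, -0.59) and MT-ATP6 (2229 to 1402 FPKM, -0.67). MT-ATP8 and MT-ATP6 overlap each other. No gene had an FPKM of 0 in one group and at least 5 in the other.

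Gene lists fixed before the data were examined were used to ask which cell functions differed between the columns. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean FPKM, which describes these 2 columns and is not a test of the conditions. Of 36 lists, 34 had at least 5 measured genes. The medians of 10 lists lay above the central 95% of the random lists and those of 3 below it, where 1.7 of 34 would fall outside by chance if genes varied independently. Genes of a list are often regulated together, so that this number is too low. Of the 46 genes that the rule named at 1.5-fold or more, 10 with low values fell below that fold with a pseudocount of 1. These were CHAC1, CLDN4, HOXB5, MX2, PMEPA1, SCG3, SNAI1, TNFAIP3, TNNT2 and WIF1. Genes chosen after their values were seen are not part of this count.

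**Figure D2:**
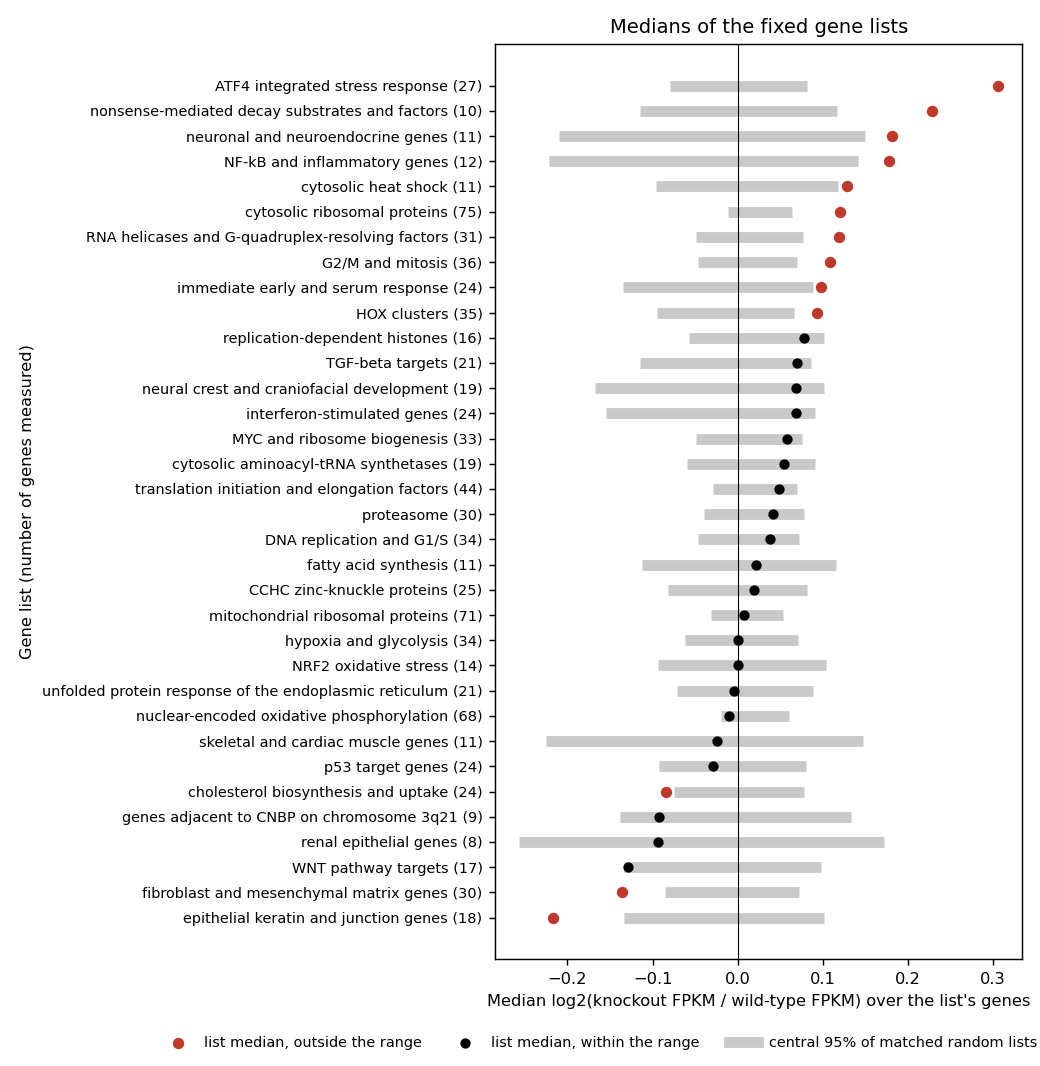
The horizontal axis is the median log2 ratio of knockout over wild-type FPKM over the genes of each fixed list, and each line on the vertical axis is a list with its number of measured genes. Grey bars span the central 95% of 10000 random lists matched on mean FPKM, and red points are the 13 medians outside it. The ATF4 list has the highest median, 0.31, and the list of epithelial keratin and junction genes the lowest, -0.22.

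The fixed list of integrated stress response genes, built around the transcription factor ATF4, stood higher in the knockout column. Of 27 measured genes, 25 had a ratio above 0, and the list's median was 0.31 (1.24-fold), above all 10000 random lists. DDIT3, which encodes the transcription factor CHOP, went from 12.3 to 21.6 FPKM (1.75-fold), DDIT4 from 43.2 to 71.2 FPKM (1.65-fold), and CHAC1, which degrades glutathione, from 2.08 to 3.27 FPKM (1.57-fold). These were the 3 that reached 1.5-fold, and none was lower by that much. With a pseudocount of 1, the log2 ratio of CHAC1 was 0.47, below 1.5-fold. DDIT3 overlaps MARS and MBD6 on the opposite strand. Further members, chosen after their values were seen, were SESN2 (log2 ratio 0.57), PPP1R15A (0.55), TRIB3 (0.46), the asparagine synthetase ASNS (0.40) and ATF4 itself (0.24). The 2 members below 0, likewise named after their values were seen, were the amino-acid enzymes CBS (-0.34) and PSPH (-0.23). CBS lies on chromosome 21, whose genes had a median log2 ratio of -0.21. The list of the unfolded protein response of the endoplasmic reticulum, another stress pathway, had a median of -0.00 over 21 genes, at the 36.0th percentile. Its most abundant members were CANX (-0.16) and CALR (0.06). Cytosolic aminoacyl-tRNA synthetases are not in the ATF4 list, and their own list had a median of 0.05 at the 81.6th percentile.

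**Figure D3:**
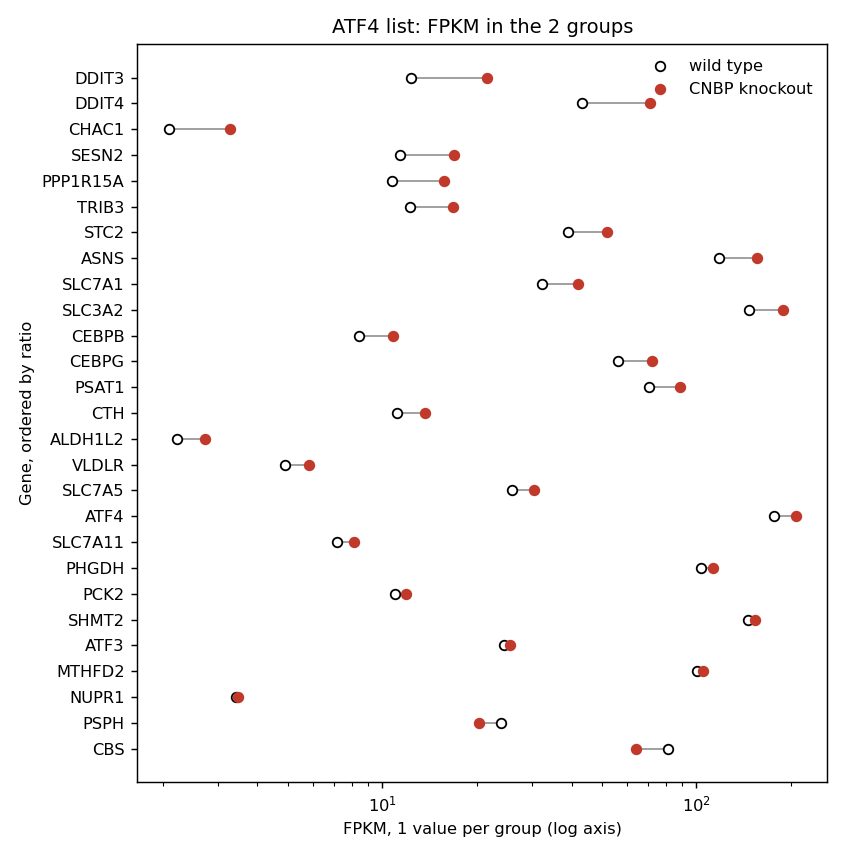
FPKM of the 27 measured genes of the ATF4 list, 1 value per group, on a log axis. Open circles are wild type and red circles CNBP knockout, and genes are ordered by their ratio from DDIT3 (1.75-fold higher) at the top to CBS at the bottom. The knockout value lies to the right for 25 of the 27 genes.

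The mRNAs of the translation machinery differed little. The cytosolic ribosomal protein genes had a median of 0.12 (1.09-fold), above all 10000 random lists, with 61 of 75 genes above 0 and none at 1.5-fold. Their most abundant members, RPLP1 and RPL23, each had a log2 ratio of 0.06. Reads of these genes are hard to assign among their many near-identical pseudogenes, and RPL41, RPS9 and RPS29, which every cell uses, were listed at 0 in both columns, so that a listed 0 can be a failed estimate. Translation initiation and elongation factors had a median of 0.05 over 44 genes (85.3th percentile), with EEF2 at 0.05 and EIF4G2 at -0.03. Cytosolic aminoacyl-tRNA synthetases had a median of 0.05 over 19 genes, with MARS at 0.09 and TARS at -0.10. The list of MYC and ribosome biogenesis genes had a median of 0.06 (91.3th percentile), with the nucleolar proteins NPM1 at 0.08 and FBL at -0.00. Proteasome genes had a median of 0.04, with PSMA3 at 0.08 and PSMA4 at -0.00.

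RNA helicases and factors that resolve G-quadruplexes had a median of 0.12 over 31 genes, at the 99.9th percentile, with 18 genes above 0 and 13 below. HNRNPH1 had a log2 ratio of -0.21 and EIF4A1, which overlaps the readthrough SENP3-EIF4A1 on the same strand, of 0.13. This list returned to the 91.1th percentile once the median of each gene's 20 nearest neighbours was taken off. The list of nonsense-mediated decay substrates and factors had a median of 0.23 over its 10 matched genes, at the 99.99th percentile, and GADD45B was its member with a ratio over 1.5-fold. The other 9 of its 19 genes, all non-coding substrates, were not matched, and ATF4 belongs to this list too. CCHC zinc-knuckle proteins, the class to which CNBP belongs, had a median of 0.02 over 25 genes. ZCCHC12 was higher (11.7 to 19.0 FPKM, 1.63-fold) and ZCCHC18, which overlaps SLC25A53 on the opposite strand, lower (3.76 to 1.88 FPKM, 2.00-fold).

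Of the lists on cell division, the mitotic genes had a median of 0.11 over 36 genes, at the 99.97th percentile, with 31 above 0 and none at 1.5-fold. The most abundant were PRC1 (log2 ratio 0.01) and TOP2A (-0.04). KIF2C, a kinesin that depolymerises microtubules, was the highest at 0.48, chosen after its value was seen. Genes of DNA replication had a median of 0.04, with MCM4 at 0.05 and MCM7 at 0.06, and the replication-dependent histones 0.08, with HIST1H4H at 0.14 and HIST1H1C at -0.02. Histone mRNAs are near-identical among copies. The p53 target genes had a median of -0.03, with MDM2 at -0.02 and CCNG1 at -0.02. HEK293 cells carry adenoviral genes whose products interfere with p53.

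Stress and signalling lists varied in size of shift. The cytosolic heat shock genes had a median of 0.13 over 11 genes (98.3th percentile), with HSPA8 at 0.15 and HSP90AA1 at 0.12. The NF-kB and inflammatory genes had a median of 0.18 over 12 genes (99.1th percentile), and TNFAIP3, an inhibitor of NF-kB signalling, went from 2.96 to 4.85 FPKM (1.64-fold). Immediate early genes had a median of 0.10 over 24 genes (98.3th percentile), and FOSB went from 1.47 to 3.13 FPKM (2.12-fold), with ERCC1 overlapping it on the opposite strand. The immediate early list fell within the range when genes below 5 FPKM were left out, and the NF-kB list when no minimum was applied. Too few NF-kB genes reached 5 FPKM for that list to be placed at that level. Interferon-stimulated genes had a median of 0.07 (94.5th percentile), with MX2 1.59-fold higher at 2.69 FPKM, and the TGF-beta targets 0.07, with PMEPA1 1.53-fold higher at 4.51 FPKM. The WNT targets had a median of -0.13 (2.89th percentile), and WIF1, a secreted WNT inhibitor, went from 1.31 to 0.625 FPKM.

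Metabolic lists were near or below 0. Genes of cholesterol synthesis and uptake had a median of -0.08 over 24 genes, at the 1.44th percentile, with none at 1.5-fold. Its most abundant members were FDPS (-0.03) and FDFT1 (-0.12), and INSIG1 had a log2 ratio of -0.40 and LSS of -0.39, both chosen after their values were seen. LSS lies on chromosome 21. Fatty acid synthesis had a median of 0.02, with ACLY at 0.02 and FASN at 0.09, and the hypoxia and glycolysis list 0.00, with GAPDH at 0.09 and ENO1 at 0.19. The NRF2 list had a median of 0.00, with FTL at 0.23 and TXN at -0.04. Mitochondrial ribosomal proteins had a median of 0.01 over 71 genes, with MRPL51 at -0.07 and MRPL20 at -0.24. Nuclear-encoded oxidative phosphorylation genes had a median of -0.01 over 68 genes, and NDUFS6, a subunit of complex I, went from 68.5 to 41.2 FPKM (1.66-fold lower).

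Lists that mark cell types or tissues lay on both sides of 0. The fibroblast and mesenchymal matrix genes had a median of -0.14 over 30 genes, at the 0.06th percentile, with 25 below 0 and none at 1.5-fold. The most abundant were VIM (0.03) and THBS1 (-0.15), and fibronectin, FN1, had -0.29, chosen after its value was seen. The epithelial keratin and junction genes had a median of -0.22 over 18 genes, at the 0.09th percentile, with CLDN4 1.51-fold lower at 1.53 FPKM in wild type and the cadherin CDH1 at -0.53, chosen after its value was seen. CDH1 lies on chromosome 16, whose genes had a median log2 ratio of -0.12. With the neighbours' median taken off, the median of the epithelial list was -0.23. The neuronal and neuroendocrine genes had a median of 0.18 over 11 genes (99.0th percentile). SCG3 (1.74-fold) and SYP (1.60-fold) were higher, while MAP2 was 2.14-fold lower. Renal epithelial genes had a median of -0.09 over 8 genes, with LRP2 at -0.23. The muscle list had a median of -0.02 over 11 genes, and TNNT2, which overlaps LAD1 on the same strand, went from 1.82 to 0.949 FPKM. Most blood cell and endothelial genes lay below 1 FPKM in both columns. Of the measured ones, CD68 had a log2 ratio of -0.06, CORO1A of 0.12, EGFL7 of 0.31 and TIE1 of 0.35.

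Of the developmental lists, the HOX genes had a median of 0.09 over 35 genes (99.7th percentile), with 21 above 0 and 14 below. HOXB6 (26.9 to 43.8 FPKM, 1.63-fold) and HOXB5 (5.43 to 8.16 FPKM, log2 ratio 0.59) were higher, and both overlap HOXB3 on the same strand. The HOX median was within the range when no minimum FPKM was applied. Neural crest genes had a median of 0.07 over 19 genes. SOX10, a neural crest transcription factor, went from 4.13 to 1.49 FPKM (2.78-fold lower) and lies across POLR2F on the opposite strand, and SNAI1 was 1.55-fold higher at 1.75 FPKM. The genes around CNBP on chromosome 3 had a median of -0.09 over 9 genes (9.4th percentile), and RAB43 was 2.14-fold lower, from 1.78 FPKM. RAB43 shares its strand and span with the readthrough ISY1-RAB43, so that its reads cannot be assigned with certainty.

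The series title raises the question whether mRNA levels differed with G-rich coding sequence. The ratios showed almost no relation to it. Over 13063 genes with an annotated coding sequence, Spearman's rho between the log2 ratio and the number of TGGAG motifs per kb was -0.02. The median log2 ratio was -0.00 in the fifth of genes with the fewest motifs and -0.02 in the fifth with the most. The coefficient was 0.01 with the percentage of G, 0.05 with the percentage of G plus C and 0.03 with coding length. These values are across genes and concern mRNA abundance. Translation and binding were not analysed here.

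Ratios also differed by place in the genome. When genes were ordered along the chromosomes, 13 of 317 windows of 40 genes had a median beyond 0.2 either way, while no window did in 1000 shuffled orders, whose extremes were -0.19 and 0.15. On chromosome 16, 420 of 622 genes were lower in the knockout column, and on chromosome 21, 111 of 125. Chromosome 6 had 399 of 582 genes lower and the X chromosome 271 of 428. On X, the window from RPL36A to PSMD10 had a median of -0.25. The window with the lowest median, -0.27, ran from NKD1 to ZNF319 on chromosome 16, and that from TMC7 to PALB2 on the same chromosome had 39 of 40 genes lower. A high window ran from RPL22L1 to DVL3 on chromosome 3, where the median was 0.22 and 37 of 40 genes were higher. The ratio of a gene in these regions includes that shift.

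**Figure D4:**
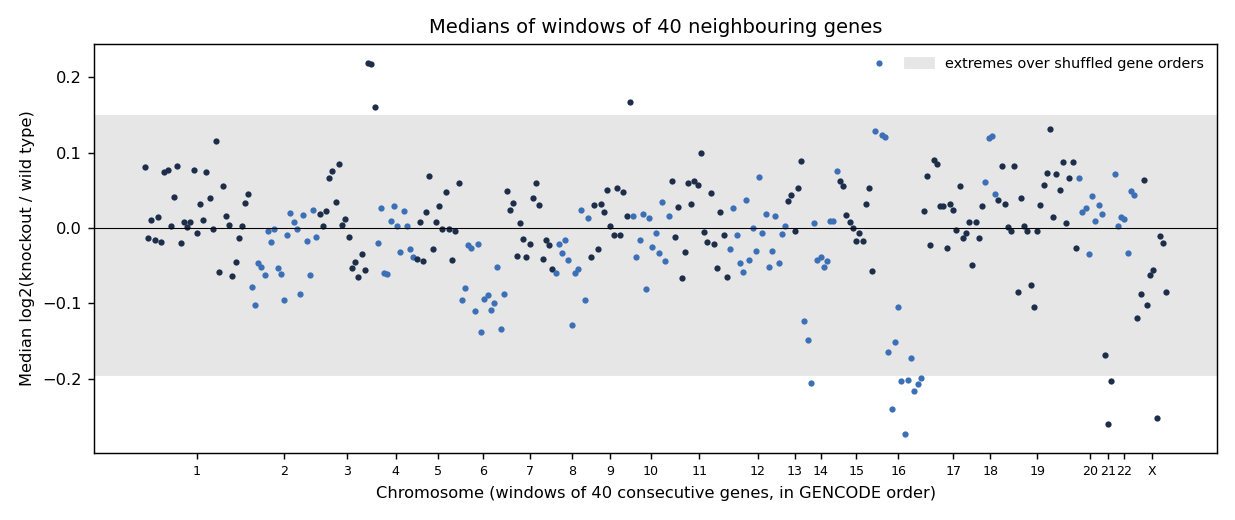
Each point is the median log2 ratio of knockout over wild-type FPKM in a window of 40 consecutive genes, on the vertical axis, against the place of the window along chromosomes 1 to 22 and X, on the horizontal axis. The grey band spans the extremes over 1000 shuffled gene orders, -0.19 to 0.15, and most windows of chromosome 16 and all of chromosome 21 lie below 0.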

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

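The 1.5-fold threshold, the 2-fold threshold, pseudocounts for the counts of genes, the neighbours' median and the exclusion of clone-named and readthrough genes were chosen after the data were seen. No paired analysis was possible because the table gives 1 value per group, and for the same reason leaving out a library and other adjusted p thresholds could not be run. Against 196 genes higher and 368 lower, the counts were 53 and 126 with an FPKM of at least 5 in one group, 945 and 1141 with no minimum, 74 and 141 with a pseudocount of 1, and 45 and 90 at 2-fold. These follow from the construction of the settings, which leave out, add or shrink ratios of low genes or ask for a larger fold. The other settings stayed within 1.5 times: 201 and 349 after centring, which moved little since the median log2 ratio was already -0.01, 174 and 328 with a pseudocount of 0.1, 193 and 335 with the neighbours' median taken off, and 172 and 354 without clone-named and readthrough genes. Leaving out small non-coding RNA genes removed none. Lower genes outnumbered higher ones in every one of these settings.

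The log2 ratio of CNBP and the rho values for coding sequence moved by less than 0.1 in every setting run. With the neighbours' median taken off, rho was -0.04 for the percentage of G and -0.01 for G plus C, and with the shortest coding sequence it was -0.00 for the percentage of G. A pseudocount of 1 moved 29 of 88 values of genes named by the rule by 0.1 or more, and the neighbours' median 15 of 85. No gene that the rule named at 1.5-fold changed sign, but some fell below that fold. These were 10 of 46 with a pseudocount of 1, CLDN4 and HOXB5 with 0.1, and MT-ND3 after centring. With the neighbours' median taken off, HOXB5, PMEPA1 and SNAI1 of 43 fell below it. Genes chosen after their values were seen, such as MT-ND6, COL9A3 and COL9A2, were not part of these counts. Of the 13 lists outside the central 95%, all 13 stayed outside with lists matched on length and with both pseudocounts, and no median of these lists changed sign. The WNT list joined them with a pseudocount of 1. With the neighbours' median taken off, 12 stayed, the RNA helicases left and the TGF-beta targets joined. At an FPKM of at least 5, the NF-kB list had fewer than 5 measured genes and was not placed, and 11 of the other 12 stayed. With no minimum, 11 of 13 stayed. The depth is unknown, and at low FPKM the wide spread of ratios limits what single genes show.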

Other observations

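The gene families and the mitochondrially encoded mRNAs described here, and the tests of the endoplasmic reticulum list and of unequal scaling, were chosen after the result was seen.

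All 13 mitochondrially encoded mRNAs were lower in the knockout column. These mRNAs can move together, and MT-ATP8 and MT-ATP6 overlap, so that the 13 are not independent results. Their median log2 ratio was -0.37, and 4 of them, MT-ATP6 (-0.67), MT-ATP8 (-0.61), MT-ND3 (-0.59) and MT-ND6 (-0.59), were lower by 1.5-fold or more. MT-CO1, at 2538 and 2510 FPKM, and MT-ND1, at 961 and 882, differed least. All 13 together made up 4.91% of summed FPKM in wild type and 3.71% in knockout. Of the 100 most abundant other genes, 35 were lower, the median was 0.08, and none was at or below the mitochondrial median. The nuclear-encoded oxidative phosphorylation genes had a median of -0.01 and the mitochondrial ribosomal proteins 0.01. Mitochondrial genes can share reads with nuclear copies, and their short mRNAs make FPKM sensitive to fragment length. The 4 at 1.5-fold were 207 to 681 bases long, and MT-ND4L, at 297 bases, had -0.44. Of the longer ones, MT-CO1 (1542 bases) had -0.02, but MT-ND4 (1378 bases) had -0.47 and MT-ND5 (1812 bases) -0.31. The 100 other genes were not matched on length, so that an effect of length is not separated from a general decrease.

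Among 80 families of at least 15 genes with a common symbol stem, 11 had medians outside the central 95% of matched random lists, where 4 would by chance. Of the 31 COL genes, nearly all collagen chains, 28 were lower in the knockout column, with a median of -0.25 below all random lists. COL9A3 (1.14 to 0.440 FPKM), COL2A1 (18.1 to 8.84 FPKM) and COL9A2 (1.90 to 1.25 FPKM) were lower by 1.5-fold or more. COL9A3 and COL9A2 had low values, where ratios spread widely, and were not part of the counts with a pseudocount. The 23 members in neither the mesenchymal nor the TGF-beta list had 20 lower and the same median, and the median of all 31 was -0.19 with the neighbours' median taken off. Of 39 ZBTB genes, mostly transcription factors with a BTB domain and zinc fingers, 29 were higher, with a median of 0.16. ZBTB43 was the 1 member above 1.5-fold, followed by ZBTB49 (0.43) and ZBTB6 (0.37).

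The ATF4 list stood higher in the knockout column, over genes on 17 chromosomes. The tables argue against transcript length bias, since the list stayed at percentile 100 among random lists matched on length as well, and against regional copy number, since its median was 0.30 with the neighbours' median taken off. A general rise of endoplasmic reticulum chaperones and their partners is argued against by that list's percentile of 36.0. Stress signals from the endoplasmic reticulum that leave those genes unchanged were not tested. Loss of CNBP, a difference between clones and a difference in nutrients or density of the cultures all stay open, untested. Each would fall between the same 2 groups, and nothing in the labels tells them apart.

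More genes were lower than higher in the knockout column, 368 against 196. Uncertain low FPKM values as the whole cause are argued against by the ratio of lower to higher genes, which was 2.38 with an FPKM of at least 5 in one group. Regional shifts as the whole cause are argued against by a ratio of 1.74 with the neighbours' median taken off. Unequal scaling of the columns stays open: the ratio was 1.74 after centring, but the median was already -0.01, so that centring moved almost nothing and decides nothing. Differences between clones and the knockout itself stay open too, untested.

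Neighbouring genes were shifted together along the chromosomes. Reads shared between overlapping or duplicated neighbours as the whole cause are argued against by genes 10 places apart. The log2 ratios of such genes had a Spearman's rho of 0.073, where shuffled orders lay within 0.017 of 0 in their central 95%. Adjacent genes had a higher rho of 0.115, so that shared reads as a part of the cause stay open. A regional difference in copy number, carried by part of the cells or by 1 of several copies, may contribute, since HEK293 has an unstable karyotype. The window farthest from 0 had a median of -0.27, between the bound of 0.3 set for a copy-number difference and the bound of 0.2 set against it, so that copy number and regional regulation cannot be told apart from these values. DNA copy number was not analysed here, and the knockout as the cause stays open, untested.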
